A study of Homo sapiens with 9 samples.

How the data were processed

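RNA of H157 cells was extracted with Trizol from cells grown with 10% serum and doxycycline, 100 ng was labelled with Cy3, and each sample was hybridised to 1 array, per the labels' protocols. The arrays held 62976 spots, of which 58717 were not controls, and 50599 distinct probes of 60 bases. Spots were quantified with Feature Extraction 10.7.3.1, per the file headers. The submitters' processing notes name Agilent Feature Extraction 10.7 and RMA, with no role stated for the latter. The intensity values that the authors deposited per array are the processed signal, which is background subtracted, the raw mean signal and the local background, per the file headers. No spot was saturated. The authors' deposited value table holds log2 values whose median was 6.73 in every column, with quartiles of 6.16 and 8.97 in every column. Set against the scanner values, each column correlated at 0.993 to 0.999 with the log2 mean signal and at 0.967 to 0.993 with the log2 processed signal. Its exact background correction and reference distribution stayed unknown, and no gene was centred.

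The main values were log2 of the processed signal minus each array's 75th percentile of it. Spots with an outlier flag were left out and spots of 1 probe were averaged. A probe was kept where it was well above background on at least 3 of the 9 arrays and had a value on all but 2 arrays at most. The brightest kept probe stood for a gene, which left 19746 features, 19187 of them measured on all arrays. Gene names were updated through a RefSeq table of assembly GRCh38.p14, used for names only. Of the probes, 28174 matched by accession, 2618 by symbol and 620 by an older symbol, and 19187 kept the name in the files. Probe coordinates are those of the files, in hg19.

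Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) in 1 fit over all 9 arrays, with 6 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The median residual SD after moderation by eBayes was 0.396 on the log2 scale. The 20 gene lists were tested with camera at a preset correlation of 0.01, adjusted over 60 list tests, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. Arrays of 1 group correlated at 0.940 to 0.989 across features and arrays of different groups at 0.952 to 0.987, so these ranges do not separate the groups. No 2 arrays were identical. The design, the lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule took, per comparison, every PARD3 probe, the 8 largest changes in each direction past the test with groups that did not overlap and a bright group above background on all its arrays, up to 3 members of each list past the test, and the 3 smallest p of a list that shifted without such a member.

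The steps were tested on simulated data for wt against mock with 19187 genes. Of 50 genes changed 2-fold 6 were recovered, of 50 changed 4-fold 42, of 50 changed 8-fold 49 and of 50 changed 16-fold 46, with 3 calls among unchanged genes. None of the 60 list tests was called without a shift, and a list shifted by 0.5 was called. The simulated genes varied independently of each other, so this does not check the list tests on correlated genes. Smaller list shifts were not simulated.

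Alternatives covered the scaling, the background correction, the deposited value table, the filter on dim probes, the choice of probe, outlier spots, the arrays in the fit, a replicate block, the slide, the variance model, array weights and each array left out. Alternatives chosen after seeing the data were another set of probes for scaling, removal of a probe GC trend (lowess span 0.5), the array signal level as a covariate, a mask on 1 array, each slide alone, and wt array 3 left out with the GC trend removed. All arrays were scanned on 1 day, so scan date was not run as a block.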

Results

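Transcript levels were measured on 9 single-colour Agilent arrays in H157, a human squamous lung carcinoma cell line that lacks PARD3. PARD3 encodes a scaffold protein of the PAR polarity complex. The cells carried a tetracycline repressor and 1 of 3 vectors, and all received doxycycline at 1 ng per µl. The mock group carried an empty vector, the wt group carried wild-type PARD3, and the mutant group carried PARD3 without exon 2. Each group had 3 arrays. The labels do not say whether the 3 came from separate cultures or clones, so p-values measure the spread between these arrays, which may be technical. Between 40.6% (mutant array 3) and 55.9% (mock array 2) of the 58717 non-control spots were well above background. The 75th percentile of the processed intensity ran from 171 on wt array 2 to 459 on wt array 3. Values below are log2 intensities relative to that percentile, and 19746 genes or unnamed transcripts were tested. The number of arrays limits the precision.

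PARD3 itself was compared first, because it checks the labels. The brightest of its 3 probes lies at 34620082 to 34620141 on chromosome 10 (hg19). It read 6.13 ± 0.48 in wt cells and 5.94 ± 0.45 in mutant cells (SD, n = 3 each), against -5.89 ± 0.26 (n = 3) in mock cells, where it was not well above background on any array. The signal was therefore at least 1102-fold higher in wt than in mock cells and at least 962-fold higher in mutant than in mock cells. These bounds set the mean of the bright group against, per array of the dim group, the higher of the lowest signal well above background and the probe's own signal. The fitted log2 differences were 12.02 (SE 0.33, limma adjusted p = 4.38e-10) and 11.82 (SE 0.33, adjusted p = 5.41e-10). A probe at 34408658 to 34420439 was also higher, by 3.65 in wt and 3.37 in mutant cells (SE 0.34 each), and was well above background on 1 of 3 mock arrays. The probe at 34635126 to 34635185 was not well above background on any of the 9 arrays. The wt and mutant groups differed by 0.20 (SE 0.33, adjusted p = 1.00) at the brightest probe. Probe positions were not placed relative to exon 2, so these probes do not check the deletion.

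**Figure D1:**
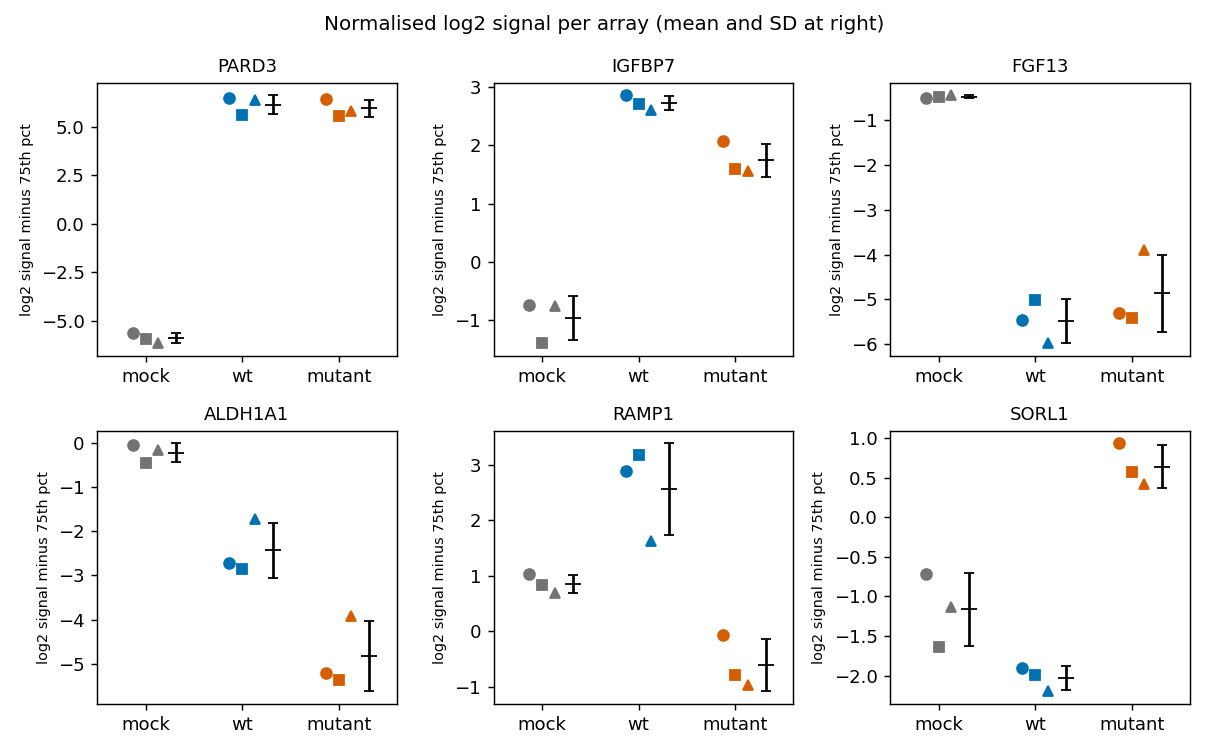
Normalised log2 signal (vertical axes, log2 intensity minus the array's 75th percentile) of 6 genes in mock, wt and mutant cells; circles, squares and triangles are replicates 1, 2 and 3, and the bar at the right of each group is the mean with its SD (n = 3). PARD3 lay at -5.89 in mock cells and at 6.13 and 5.94 in wt and mutant cells, and FGF13 lay at -0.47 in mock cells and at -5.49 and -4.87 in wt and mutant cells.

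The first comparison set cells with wild-type PARD3 against mock cells. Each group carried its own vector, all samples received doxycycline, and no uninduced cells were included. An effect of PARD3 therefore cannot be told apart from differences between separately derived cell populations. Here and below, rose and fell describe differences between the groups only. IGFBP7, a secreted insulin-like growth factor binding protein, rose by 3.70 on the log2 scale (SE 0.29, limma adjusted p = 7.95e-05), a 13.0-fold change, from -0.97 ± 0.38 to 2.73 ± 0.13 (SD, n = 3 each). FGF13, a fibroblast growth factor homologous factor on chromosome X, was at least 8.65-fold lower in wt cells, where it was not well above background on any array. In all, 67 genes changed, 41 of them higher and 26 lower in wt cells, each with a fitted difference of at least 2-fold. For genes not read in 1 of the groups only the bounds hold, and these can be smaller. Other genes that rose were COXFA4L3 (C15orf48 in the array's annotation, 2.91), CAMK1D, a calcium and calmodulin-dependent kinase (2.71), NLRP5 (2.79) and NRCAM, a neuronal cell adhesion molecule (2.62). NLRP5 was well above background on 2 of 3 mock arrays. KIR2DS2, FOXJ1 and PTPN22 were not well above background in mock cells and were at least 3.75-fold, 2.44-fold and 2.94-fold higher in wt cells.

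The other named genes with a lower signal in wt cells were read in mock cells but not in wt cells. PCDH7, a protocadherin, was at least 3.65-fold lower and HECW2, a ubiquitin ligase, at least 4.96-fold lower. The receptor tyrosine kinases TIE1 and ERBB4 were at least 4.28-fold and 2.25-fold lower. AGMO, which cleaves alkylglycerols, was at least 2.80-fold lower, CPE, a carboxypeptidase of prohormone processing, at least 4.01-fold lower, and CBLN2 at least 1.83-fold lower. None of these 7 was well above background on a wt array. In the fixed list of mesenchymal genes COL5A1, a fibrillar collagen chain, rose by 1.74 (SE 0.30, adjusted p = 0.0226). PTPN22 and ERBB4 lost their calls in 12 and 11 of 29 alternatives and COL5A1 in 11 of 30. COL5A1 was 1 of 20 measured members past the test, over all genes and adjusted over the list alone. FOXJ1, a ciliated cell regulator, was the 1 member past the test among 12 measured markers of other cell types.

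As sets, 4 of the 20 fixed lists shifted in this comparison with a preset correlation (camera). The 16 measured NF-kB-driven cytokines and regulators had a median of 0.62 (adjusted p = 1.57e-06), with 14 values above 0. None passed the test over all genes, and 4 (CXCL1, CXCL2, CXCL3 and IL6) were higher adjusted over the list alone. CXCL1, a neutrophil chemokine, had a value of 1.43 (SE 0.28, adjusted p = 0.0554), IL6 a value of 1.33 (adjusted p = 0.0817) and CXCL3 a value of 1.26 (adjusted p = 0.226). The 22 interferon-stimulated genes had a median of 0.44 (adjusted p = 0.000924), with 18 values above 0 and none past the test. Examples were IFIT1 at 0.90, ISG20 at 0.96 and IFI44 at 0.99. In mutant against mock the interferon list had a median of 0.33, with 14 values above 0, and did not pass (camera adjusted p = 0.233). In wt against mutant it had a median of 0.10 and did not pass either (adjusted p = 0.117). The interferon shift is thus not shown to be particular to wild-type PARD3. The 17 heat shock genes had a median of -0.37 (adjusted p = 0.000918), with 15 values below 0. Across the alternatives that median ran from -0.55 to -0.22. HSPA1A, at -1.35 and not well above background in wt cells, passed adjusted over the list alone, and HSPA8 stood at -0.73 and HSPH1 at -0.62. The 28 cell cycle genes had a median of -0.23 (adjusted p = 0.0034), with 24 values below 0 and none past the test. PCNA stood at -0.43 and MKI67 at -0.60, while the 3 probes of RRM2 disagreed, the brightest at -0.81 and the others at 0.78 and 1.37. In mutant against mock the cell cycle list had a median of -0.28 and did not pass (camera adjusted p = 0.0603). In wt against mutant it had a median of 0.01 (adjusted p = 0.65). Its shift is therefore not shown to be particular to wild-type PARD3. With an estimated correlation none of the 4 calls held, the adjusted p being 0.18 for the cytokine and interferon lists, 0.283 for heat shock and 0.596 for cell cycle genes. In the same order the estimated correlations were 0.09, -0.02, 0.07 and 0.13, against the preset 0.01. For the interferon list, correlation between its genes thus does not account for the lost call. The test with an estimate also rests on only the 6 residual degrees of freedom.

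**Figure D2:**
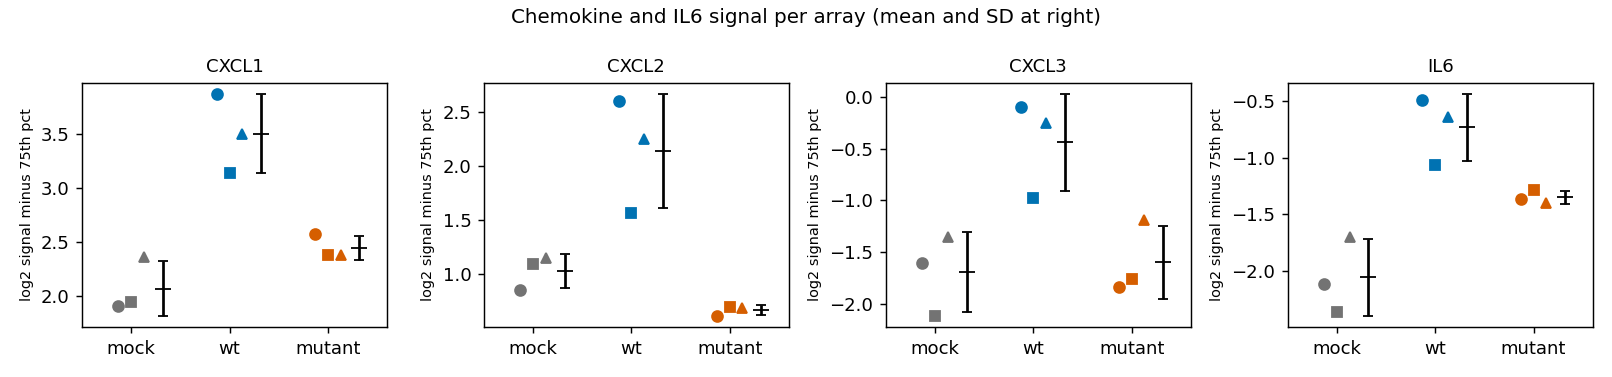
Normalised log2 signal (vertical axes, log2 intensity minus the array's 75th percentile) of CXCL1, CXCL2, CXCL3 and IL6; circles, squares and triangles are replicates 1, 2 and 3, and the bar at the right of each group is the mean with its SD (n = 3). CXCL1 lay at 3.50 in wt cells and 2.07 in mock cells, a difference with an adjusted p of 0.0554.

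The count of 67 depended on single arrays, and its balance on the background correction and the filter. With normexp and the 75th percentile, and also with the filter on all 9 arrays, 39 genes were higher and 9 lower. It was 1590 without wt array 3, 28 without wt array 1, 28 without mock array 2 and 39 without mock array 3. The arrays lay on 2 slides. With the slide as a block 66 genes were called, against 4 within slide 1, which held 1 mock array, and 12 within slide 2, which held 1 wt array. The within-slide tests below therefore have an arm of 1 array, except mutant against mock within slide 2, which has 2 arrays in each arm. The spread was taken from all 9 arrays (3 pairs of the same group and slide). The NF-kB list had medians of 0.50 and 0.79 within the slides, and heat shock genes -0.32 and -0.27, each past the test. The interferon list did so in slide 1 (0.31, adjusted p = 0.000107) but not in slide 2 (0.38, adjusted p = 0.255), and the cell cycle list likewise (-0.24, adjusted p = 0.0265, and -0.23, adjusted p = 0.144). With the slide as a block the 4 medians were 0.64, 0.51, -0.27 and -0.20, in the order NF-kB, interferon, heat shock and cell cycle, each past the test. Without wt replicate 3 the interferon list had a median of 0.51 and did not pass (adjusted p = 0.0906), nor did it with array weights (0.43, adjusted p = 0.11). The cell cycle list had a median of -0.14 with array signal level as a covariate (adjusted p = 0.0957).

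The second comparison set cells with PARD3 without exon 2 against mock cells, with the same limit. ARHGAP22, a Rac GTPase-activating protein, rose by 3.72 (SE 0.31, limma adjusted p = 0.000245), and CADM1, a cell adhesion molecule, rose by 3.46 (SE 0.34, adjusted p = 0.000621). They were well above background on 1 and 2 of 3 mock arrays. ALDH1A1, a retinaldehyde dehydrogenase, was at least 7.17-fold lower (adjusted p = 0.00026) at its brightest probe, which was not well above background on any mutant array, although its second probe read -0.02. FGF13 was at least 6.05-fold lower. In all, 72 genes changed, 39 higher and 33 lower in mutant cells, each with a fitted difference of at least 2-fold, though bounds against background can be smaller. IGFBP7 rose by 2.71, XAGE2, a cancer-testis antigen listed as XAGE2B, by 2.59, and CYB5R2, a cytochrome b5 reductase, by 2.52. SELENBP1, OR10W1 and KCNE1 were not well above background in mock cells and were at least 5.39-fold, 4.96-fold and 3.74-fold higher. These 3 genes were well above background on mutant arrays only, and OR10W1 and XAGE2 had values on 2 mutant arrays (n = 2). SELENBP1 and KCNE1 sat in array column 32, at the edge of a region of mutant array 3 where dim spots were bright. For SELENBP1, mutant against mock without mutant replicate 3 gave 3.32 (adjusted p = 0.0196). For KCNE1, mutant against mock without mutant replicate 3 gave 2.34 (adjusted p = 0.0403), and for OR10W1, mutant against mock without mutant replicate 3 gave 2.79 (adjusted p = 0.169), with 1 mutant array left that had a value. Without mutant replicate 1, KCNE1 had an adjusted p of 0.0601. OR10W1 lost its call in 15 of 29 alternatives, MAGEC1 in 14 and KCNE1 and LIN7A in 10 each.

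Among the genes that fell in mutant cells, DACH1, a transcription cofactor, was at least 6.52-fold lower and PTGIS, prostacyclin synthase, at least 4.28-fold lower. CPE, LIN7A and ACSS3 were at least 2.80-fold, 2.32-fold and 1.99-fold lower. LIN7A encodes a PDZ-domain scaffold protein of cell junctions. MAGEC1, a cancer-testis antigen, was at least 1.98-fold lower (adjusted p = 0.024). It had a value on 2 mutant arrays and was not well above background on either. No member of the 20 lists passed the test over all genes in this comparison. Adjusted over each list alone, MAGI1, IFIT1, EDN1 and CHGA were higher and BST2 was lower.

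The lists that shifted in mutant cells were heat shock genes, with a median of -0.39 over 17 genes (adjusted p = 0.0328), and ERK feedback and target genes, with a median of -0.41 over 19 genes (adjusted p = 0.0304). In the first, 14 values lay below 0, among them HSPA4L at -0.71 and CHORDC1 at -0.57, while HSPB1 stood at 0.56. In the second, 16 values lay below 0, among them DUSP6 at -0.73 and EGR1 at -0.74, while IER3 stood at 0.61. Both had an adjusted p of 0.596 with an estimated correlation. Neither passed within slide 1, a test of 1 array against 1 that decides little (-0.32, adjusted p = 0.111, and -0.55, adjusted p = 0.0559) or within slide 2 (-0.12 and -0.30, adjusted p = 0.144 for both). With the slide as a block they read -0.39 and -0.41, both past the test. Mutant array 3 stood apart, with the lowest share of spots above background, and without it the medians shrank to -0.21 and -0.26 and neither passed (adjusted p = 0.0912 and 0.12). Neither passed without mock replicate 3 (-0.36 and -0.33, adjusted p = 0.0895 and 0.0748) or with quantile normalization (-0.55 and -0.40, adjusted p = 0.0525 and 0.128). The heat shock list also did not pass without mock replicate 1 (-0.37, adjusted p = 0.0613), nor the ERK list without mutant replicate 1 (-0.34, adjusted p = 0.0826). Both calls were also lost with array signal level as a covariate and with the mask on mutant array 3. The heat shock call was lost with the probe GC trend removed. Over 32 settings the 2 lists lost their calls in 13 and 12, with medians of -0.75 to -0.12 and -0.77 to -0.24.

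The count of 72 was 41 without mock array 1, 25 without mock array 2, 43 without mock array 3, 115 without wt array 2 and 147 without wt array 3. It was 72 with the slide as a block, 135 within slide 1 (128 higher and 7 lower), which held 1 mutant and 1 mock array, and 61 within slide 2. Without a filter 70 genes were higher and 14 lower. Scaling to the median left the median of all genes at -0.34, against 0.02 before, and gave 26 genes higher and 56 lower, and quantile normalization gave 27 higher and 47 lower.

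Comparisons with the same mock arrays were set side by side. Leaving out PARD3, 15 genes were higher and 12 lower in both wt and mutant cells, and none was called in opposite directions. IGFBP7, NRCAM, CADM1, ARHGAP22, CAMK1D and CYB5R2 were among the former, and FGF13, AGMO, CBLN2, CPE, ERBB4 and ALDH1A1 among the latter. Independent lists of these lengths would share 0.077 and 0.0435 genes. In 100 simulations of unchanged groups against shared mock arrays none was called in both. Unchanged groups give few calls at all (0 in mutant against mock in the simulated data described above). The simulated 0 is therefore no measure for the shared calls. Across genes, which are not independent replicates, the 2 sets of log2 differences correlated at r = 0.65, against a mean of 0.50 in the simulations. The correlation was 0.35 without wt replicate 2 and 0.47 with array signal level as a covariate, settings for which no unchanged groups were simulated. With r this dependent on single arrays, its distance from the simulated mean does not show an excess. In the full set the covariance was 0.155 against 0.0767 simulated. Both sets used the same 3 mock arrays, too few to divide, so part of the overlap may come from the shared controls. The simulated groups were unchanged. They therefore cannot tell a shared response to PARD3 from mock cells or mock arrays that differ as a group.

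The third comparison asked how the wild-type and mutant forms differed, and it is also the test of whether their effects against mock differ. RAMP1, a receptor activity-modifying protein for calcitonin-family receptors, was higher in wt cells by 3.17 (SE 0.39, limma adjusted p = 0.00532). It read 2.56 ± 0.82 in wt and -0.60 ± 0.48 in mutant cells (SD, n = 3 each). SORL1, a sorting receptor, was 2.67 lower in wt than in mutant cells (SE 0.30, adjusted p = 0.00341). On the mock arrays it read -0.72, -1.64 and -1.14, between the wt mean of -2.03 and the mutant mean of 0.64. In all, 36 genes differed, 25 higher and 11 lower in wt cells, each with a fitted difference of at least 2-fold. PRXL2A (C10orf58 in the annotation) was higher by 2.87 and HSPA12A by 2.71, and these were well above background on 2 and 1 of 3 mutant arrays. HBE1, the embryonic beta-like globin, was at least 3.46-fold higher in wt cells. PTGIS, GALC, DLG3 and GAREM1 (FAM59A in the annotation) were at least 2.52-fold, 2.27-fold, 2.75-fold and 2.22-fold higher. GALC is a lysosomal galactosylceramidase, DLG3 a scaffold protein of the membrane-associated guanylate kinase family. None of these 5 was well above background on a mutant array. In mock cells PTGIS (mean -0.97, against -1.73 in wt cells) and DLG3 (-2.47, -2.18 and -2.01) were well above background on all 3 arrays. For PTGIS and DLG3 the difference thus lay mainly in a lower signal in mutant cells. HBE1 was also read on all 3 mock arrays (-3.20, -2.46 and -2.74), between its wt and mutant values. The second probe of GALC gave 0.563. Calls were lost in 8 of 29 alternatives for GALC and DLG3, in 12 for GAREM1 and in 17 for SELENBP1. HECW2 and SELENBP1 were at least 4.60-fold and 4.02-fold lower in wt cells. For SELENBP1, wt against mutant without mutant replicate 3 gave -2.73 (adjusted p = 0.0833).

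BST2, an interferon-induced membrane protein, was 2.00 higher in wt than in mutant cells (SE 0.33, limma adjusted p = 0.0254), a call lost in 12 of 30 alternatives. It was the 1 member past the test among 22 interferon-stimulated genes, whose list did not shift (adjusted p = 0.117), although it passed with normexp and the 75th percentile (0.0203), without a filter (0.0181) and with the filter on all 9 arrays (0.00596). The NF-kB list shifted again, with a median of 0.51 over 16 genes (adjusted p = 1.54e-06) and 14 values above 0. CXCL2 stood at 1.48 (adjusted p = 0.0887), CXCL1 at 1.06 and CXCL3 at 1.16. CXCL1, CXCL2, CXCL3 and CXCL8 were higher adjusted over the list alone. The 25 cholesterol synthesis genes had a median of 0.29 (adjusted p = 0.00206), with 20 values above 0 and none past the test. INSIG1 stood at 0.97 and MSMO1 at 0.88. With an estimated correlation the adjusted p was 0.18 for the NF-kB list and 0.283 for the cholesterol list. Adjusted over the list alone, 5 mesenchymal genes differed, COL5A1, COL5A2 and TWIST2 higher and COL1A1 and TAGLN lower in wt cells, as did JUP, lower, DUSP6 and EGR1, higher, CHGA, lower, and FOXJ1, higher. The ERK list had a median of 0.09 in this comparison and did not pass (adjusted p = 0.057), but it passed with the slide as a block (0.17, adjusted p = 0.0146) and under other alternatives.

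The NF-kB shift was 0.51 within slide 1 and 0.61 within slide 2, and 0.55 with the slide as a block, each past the test. The cholesterol shift was 0.42 in slide 1 (adjusted p = 0.0388), 0.23 in slide 2 (adjusted p = 0.309) and 0.32 with the block. It did not pass without mutant replicate 1 (0.34, adjusted p = 0.0888) or with array weights (0.25, adjusted p = 0.202). The count of 36 was 37 with the slide as a block, 157 within slide 1 (10 higher and 147 lower, the opposite balance), where the 1 mutant array was mutant array 3, and 4 within slide 2. It was 15 without wt array 1. Quantile normalization and median scaling each gave 39 higher and 9 lower.

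The lists that did not shift in any comparison included those closest to the known role of PARD3. Of 19 measured genes of the cell polarity complexes none passed in any comparison, with medians of -0.17, -0.22 and 0.03 for wt against mock, mutant against mock and wt against mutant. The scaffold genes LIN7A and DLG3, called in mutant against mock and in wt against mutant, were not on this list. The 19 tight junction components had medians of -0.19, -0.23 and -0.00369, and the 15 genes of adherens junctions and desmosomes -0.29, -0.24 and -0.04. The smallest adjusted p among these 3 lists was 0.0739, for the adherens junction list in wt against mock. Under some alternatives these lists did pass. The adherens junction list did so in wt against mock with the 2 normexp settings (adjusted p = 0.0118 and 0.0493), with the filter on all 9 arrays (0.0344) and without mock replicate 2 (0.0415). The polarity list did so in wt against mock with normexp and the 75th percentile (0.0481) and without a filter (0.014), and in mutant against mock without a filter (0.019). In the same order, STAT3 pathway and target genes had medians of 0.10, -0.08 and 0.16 (adjusted p = 0.613, 0.447 and 0.104), and extracellular proteases and inhibitors 0.11, -0.12 and 0.26 (adjusted p = 0.447, 0.511 and 0.0739). In wt against mutant the protease list passed with the 2 normexp settings (0.0329 and 0.0357), array weights (0.014), the mask on mutant array 3 (0.0311) and slide 2 alone (0.013), and the STAT3 list with normexp and the 75th percentile (0.0329) and without a filter (0.000985). Mesenchymal genes had medians of 0.06, -0.02 and 0.00456, YAP/TEAD targets -0.23, -0.09 and 0.08, and p53 targets -0.00243, -0.16 and 0.23. Unfolded protein and amino acid stress genes had -0.15, -0.17 and 0.02, hypoxia and glycolysis genes -0.10, -0.09 and 0.00278, and NRF2 targets -0.01, 0.00265 and 0.14. Squamous and keratinocyte genes had 0.30, 0.43 and -0.18, TGF-beta targets 0.20, 0.04 and -0.03, and markers of other cell types 0.29, 0.28 and -0.05. Of the lists in this paragraph only the tight junction and mesenchymal lists passed under no alternative in any comparison. In 12 of the 60 list tests, none of them past the threshold, the median, mean and test differed in sign.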

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

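The tests of wt array 3 on its probe GC trend and on its label were chosen after the result was seen. Groups of 3 are too small for a test of outlying samples, so none was run.

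The wt and mutant effects against mock differed by the test of the difference itself in 36 genes. Among the named ones, HBE1 differed by 3.81 on the log2 scale, PTGIS by 3.36, RAMP1 by 3.17, GALC by 2.92, DLG3 by 2.87, PRXL2A by 2.87, HSPA12A by 2.71, GAREM1 by 2.64 and BST2 by 2.00, all higher in wt cells. SELENBP1 differed by -2.99, HECW2 by -2.97 and SORL1 by -2.67. HBE1, PTGIS, GALC, DLG3 and GAREM1 were not well above background on any mutant array, nor SELENBP1 and HECW2 on any wt array, so their values are distances to background and only bounds of 3.46-, 2.52-, 2.27-, 2.75-, 2.22-, 4.02- and 4.60-fold hold. ALDH1A1, named in another comparison, had a value of 2.40, also against background in mutant cells, and its second probe did not follow in mutant against mock (-0.02). The NF-kB list differed by a median of 0.51 and the cholesterol synthesis list by 0.29, with adjusted p of 0.18 and 0.283 with an estimated correlation.

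With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In wt against mock the real split called 67 genes and the highest other split 1. In mutant against mock these were 72 and 1, and in wt against mutant 36 and 2. In each case 1 split, the real one, reached the real count. The list shifts stood apart less. For wt against mock 4 lists shifted and the highest other split also gave 4, with 3 of the 10 splits as high. For mutant against mock 2 lists shifted, the highest other split gave 4 and 5 splits were as high. For wt against mutant 2 lists shifted, the highest other gave 3 and 4 splits were as high.

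The 35 dark corner control spots per array had a 95th percentile of 9.28 (log2 intensity) on mutant array 1 and 10.5 on mutant array 2, against at most 5.52 on the mock arrays. On these 2 arrays 697 and 1222 spots carried a non-uniformity flag.

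The count of genes in wt against mock rose from 67 to 1590 when wt array 3 was left out. The first principal component, 44.9% of the variance, followed the array's signal level (Pearson r = 0.959, exact permutation p = 1.65e-05, and Spearman rho = 0.983, exact permutation p = 4.96e-05, over 9 arrays, 1 relation computed, and r = 0.92 without the 2 arrays farthest from the median), with wt arrays 2 and 3 at its ends. On this component the mock arrays stood at 15.5, 34.8 and 52.5 and the mutant arrays at -26.3, -22.6 and -29.5. The 75th percentile in log2 was 8.37, 8.69 and 8.74 on the mock arrays and 8.16, 8.21 and 7.75 on the mutant arrays. Signal level thus also differed between the groups in mutant against mock. The same held for wt against mock once wt array 3 was left out. The component put wt arrays 1 and 2 at -23.8 and -73.3, with 75th percentiles of 7.93 and 7.41, below every mock array. Group and signal level then ran together, so the 1590 calls are not shown to be an effect that wt array 3 masked. A trend with probe GC content does not account for the whole rise, since 862 genes were still called without wt array 3 after it was removed, against 98 with all arrays. A difference in signal level may account for part of it: over the 1493 newly called genes measured on all arrays, the deviation of wt array 3 from the other wt arrays correlated across genes at 0.39 with the slope on signal level within the other groups (0.51 with mutant array 3 left out of the slope). A mock sample under a wrong label is excluded by PARD3, which read 6.36 on wt array 3. A mutant sample does not account for it either, since 36 genes were called in wt against mutant with wt array 3 in place and at most 1 with any mutant array in its place. That test replaced an earlier one that decided nothing, in which 30 of 44 genes called without wt array 3 had it on the wt side. No biological explanation was tested, since the design names none within a group.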

How the results depend on the processing

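PARD3 kept its direction and call against mock under each alternative that gave it a value (the filter on all 9 arrays removes it), from 7.63 to 12.48 (wt) and 7.38 to 12.03 (mutant). Its wt against mutant value ran to 0.63 with array weights, past the test, and to -0.054 with wt array 3 left out and the probe GC trend removed. Leaving out each array gave 28 to 1590 genes (wt against mock), 25 to 147 (mutant against mock) and 15 to 54 (wt against mutant), PARD3 values of 11.86 to 12.29, 11.571 to 12.005 and 0.01 to 0.47, a correlation of the 2 effects of 0.35 to 0.72, and 6 to 12 lists shifted against 8. In the order of those comparisons, normexp with the 75th percentile gave 48, 26 and 12 genes, normexp with quantile normalization 54, 31 and 21, no filter 10, 84 and 3, and the filter on all 9 arrays 48, 26 and 11. Trend and robust eBayes gave 97, 96 and 61, and array weights 10663, 3565 and 3981, with the weight estimate not converged and wt array 1 at a weight of 745. The cause of these shifts was not tested. Chosen after seeing the data, the signal level as a covariate gave 60, 41 and 85 genes and a correlation of 0.47, slide 1 alone 4, 135 and 157 and a correlation of 0.52, slide 2 alone 12, 61 and 4, wt array 3 left out with the GC trend removed 862, 160 and 46, and the mask on mutant array 3 79, 77 and 42. Lists shifted were 19 and 13 with the 2 normexp settings, 28 without a filter, 13 with the filter on all arrays, 5 with array weights, 4 in slide 2, 4 with wt array 3 left out and the GC trend removed, 3 with fry and 0 with an estimated correlation. fry kept the NF-kB list in wt against mock and against mutant and the interferon list in wt against mock.

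The replicate block gave 99, 111 and 58 genes, against 67, 72 and 36 without it. Same-numbered arrays correlated at -0.10 to 0.41 in their deviations from group means, and 5 of 9 pairs exceeded 0.1. The pairs among replicate 1 arrays stood at 0.21 to 0.23, and the highest, 0.41, was mock array 3 with wt array 3. Other pairs ran from -0.48 to 0.37, and mock array 1 correlated most with wt array 2, at 0.37. A pairing by number was thus neither established nor excluded, and the main fit kept the planned model without it. RRM2 turned to 0.45 with the mean of all probes, since its probes disagree, and HSPA4L to 0.037 within slide 1. Named genes kept their side of the threshold in 1758 values, lost it in 234, gained it in 40 and turned in 2, and the shifted lists kept theirs in 210 and lost it in 46. Scan date was not run.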

Other observations

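The tests of the NF-kB list and the mutant-only probes were chosen after their results were seen, as was the choice of the chromosome 11 window. The bounds for that window were written after its median was seen and before its share of genes and its values with the GC trend removed were seen.

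Neighbouring genes differed in the same direction between wt and mutant cells in some windows by camera with a preset correlation, but no window passed with an estimated correlation (adjusted p = 0.998 for the chromosome 11 window, 0.155 with the probe GC trend removed). In windows of 20 Mb (hg19) with at least 30 genes, 156 per comparison, 11 windows passed camera in wt against mutant. The 55 genes at 20 to 40 Mb of chromosome 11 had a median of 0.48 (adjusted p = 1.44e-09), with 47 higher in wt cells. The 86 genes at 80 to 100 Mb of chromosome 1 had 0.34 (adjusted p = 2.45e-08), with 70 higher, and the 73 genes at 60 to 80 Mb had 0.30 (adjusted p = 0.000162). In all 3 windows each mutant array lay below every other array. The lowest of the other arrays in the chromosome 11 window stood at -0.03, and the mutant arrays at -0.17, -0.30 and -0.36.

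A trend with probe GC content does not account for the chromosome 11 window, whose median was 0.40 with the trend removed (adjusted p = 1.59e-08). Array signal level was not tested for the windows. In the chromosome 11 window wt arrays 1, 2 and 3 stood at 0.13, -0.03 and 0.53 and the mock arrays at 0.10, 0.04 and 0.22. The size of the median thus depended in part on wt array 3, the brightest. A different copy number in the mutant cells cannot be told apart from regulation over a region. The share of the window's genes lower in mutant than in wt cells, 85.5%, follows from the median that picked the window, and no DNA data were analysed here. An earlier form of the hypothesis, that large segments account for genes lost or gained in both PARD3 groups, could not be decided: 15 windows shifted by at least 0.3 against mock, but 0 did with the trend removed.

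The NF-kB list had a higher median in wt cells than in both other groups by camera with a preset correlation, with no member past the test over all genes and an adjusted p of 0.18 for both with an estimated correlation. Signal level is argued against, because wt array 3, the brightest, and wt array 2, the dimmest, stood at 0.36 and 0.31 for the list's median deviation, above the highest mock or mutant array at 0.04. That test replaced an earlier one, in which the shift against mock with signal level as a covariate was 0.32, only just above its bound of 0.31. The GC trend is argued against, with a shift of 0.59 once removed, and so is the slide, since the shift was 0.64 with the slide as a block and wt arrays on both slides lay above every other array. The lower of the within-slide shifts, each with an arm of 1 array, was 0.50. A response to wild-type PARD3 is one hypothesis, which the same wt cells with and without doxycycline at equal density would test. Differences between separately derived cell populations or in culture density stay open and untested.

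Of the 8 probes well above background on all 3 mutant arrays and on no other array, 7 lay in array columns 1 to 32, which held 20.1% of the dim probes (exact binomial p = 8.76e-05). A probe enters this set only if it is bright on mutant array 3, so its position largely follows from that array's bright region. The p-value therefore decides nothing further. If the 3 mutant arrays were independent, 3.38 such probes would be expected. On mutant array 3, 15.3% and 17.7% of dim spots were above background in columns 1 to 16 and 17 to 32, and 1.08% in columns 33 to 48.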
